A study of Homo sapiens with 6 samples.

How the data were processed

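RNA was measured by strand-specific RNA-seq of total RNA in 6 libraries of DND41 cells, a human T-cell acute lymphoblastic leukaemia (T-ALL) line that is known to carry activating NOTCH1 mutations. Per the labels, 3 libraries came from cells treated with MB1-47 and 3 from cells treated with its solvent DMSO, for 24 h in serum-containing medium. The labels give the dose of MB1-47 as 4 mM; the unit is repeated as written there and was not checked. The labels say that cells were plated in triplicates and do not say more about how far the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical in part.

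The deposited table gives 1 value per gene symbol and library, and per the labels these values are normalized counts, used here as a signal that is never negative. Per the submitters' processing notes, kallisto 0.44.0 and DESeq were used with the genome build GRCh38.p13; the annotation, the way transcripts were summed to genes and any filter are not given in the sources used here. kallisto estimates how many reads each transcript received by comparing reads with transcript sequences, and it splits reads that fit several transcripts. Values of genes with near-identical copies, such as histones, ribosomal proteins, read-through transcripts and nuclear copies of mitochondrial genes, are therefore uncertain. The table held 17202 genes, 14559 of them protein-coding in GENCODE 29 and most others pseudogenes.

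The deposited values are not whole numbers. Between 11.4% and 64.8% of the low values of a library lay within 0.1 of a whole multiple of a common step, so whole reads were not recovered, the depth of each library is unknown, and no counting interval or floor is given. The totals of the normalized values ran from 28323700 to 32667500 per library and are not depths. No value above 0 was shared by any pair of libraries in the same gene, and library correlations on the log2 scale ran from 0.953 to 0.964 within groups and from 0.939 to 0.953 between groups, so no library was counted as a duplicate.

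Genes with a mean of at least 10 over the 6 libraries were tested, which left 13465 genes. Values were taken as log2(value + 1), so a fold change is on that scale and understates the change of low genes. limma 3.58.1 in R 4.3.3 fitted the group difference per gene with its moderated test and an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All adjusted p-values of genes come from this fit. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 32 lists that had at least 5 tested members; the list of myeloid and erythroid markers had 3 and was not tested. Each list was tested again with a correlation estimated from the data and with limma's fry. Of 942 list entries, 825 matched the table by symbol and 53 by an older symbol or synonym.

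The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with an HGNC symbol in GENCODE 29, a mean of at least 100 and no overlap between the groups; from each list up to 3 members past the threshold with the largest change and a mean of at least 50; and MYC, NOTCH1, HES1, DTX1, ATF4, DDIT3, TXNIP, CDKN1A, MKI67, PPARGC1A, UCP2 and TFAM in any case. The rule named 115 genes, some of which are not reported here. Further genes are named to complete a count of 5 or fewer or to describe a group; these were chosen after their values were seen, and are called added where they appear. Gene positions are those of GENCODE 29 on GRCh38, where 99.1% of the table's symbols were found once.

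The steps were tested on simulated data with 200 changed genes among 13465 for the comparison of MB1-47 with DMSO. They recovered 29.9% of genes changed by 1.5-fold, 64.2% of those changed 2-fold and 95.5% of those changed 4-fold with the right sign, and 6.67% of the calls were unchanged genes. Both seeded lists and 0 of 30 unchanged lists were called. Genes were drawn independently of each other, so the simulation does not show how often lists of correlated genes are called in error. The 200 changed genes are also far fewer than the 5125 called in the data, where recovery may differ.

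The alternatives were a pseudocount of 0.5 or 5, no filter or a filter at 50, factors from the trimmed mean of M values computed on the deposited values, quantile normalization, limma without a trend, the replicate number as a block, and each library left out in turn. Equal library totals and removal of each library's trend on GC content and transcript length were added after the data were seen. Count-based tests were planned only in case whole reads could be recovered and were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.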

Results

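The data were gene-level RNA-seq values of DND41 T-ALL cells after 24 h with MB1-47, which the series title describes as a drug that uncouples mitochondria, or with DMSO, with 3 libraries in each group. A mitochondrial uncoupler lets protons return across the inner membrane without making ATP. The design implies a single comparison, MB1-47 against DMSO, which asks how the transcripts of these leukaemia cells differed after treatment. The first principal component held 43.0% of the variance and separated the groups, and the second held 18.5% and set DMSO replicate 1 apart from the other DMSO libraries. Values are deposited normalized counts, changes are log2 fold changes of MB1-47 against DMSO ± SE, and group levels are mean ± SD (n = 3). These are relative levels: the labels used here name no spike-in, and RNA per cell was not measured.

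MB1-47 changed a large part of the transcriptome. Transcripts for growth, DNA replication, glycolysis and mitochondrial respiration were lower, and transcripts of the endoplasmic reticulum stress response, the integrated stress response and FOXO-linked growth arrest genes were higher. Of the lists behind that sentence, only ribosome biogenesis and DNA replication passed when the correlation between genes was estimated from the data. Of 13465 genes tested, 5125 passed the threshold, 2458 higher and 2667 lower with MB1-47, and 1446 of them changed at least 2-fold (640 higher, 806 lower). The groups did not overlap in 49.3% of tested genes, against 10% by chance for 3 against 3. The split between higher and lower depended on scaling: with each library scaled to the same total, the median of all genes moved from 0.02 to 0.15 and the split became 3336 higher and 2061 lower.

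Among genes with a mean of at least 100 and no overlap between the groups, the largest rises were those of TCP11L2, YPEL3, UNC5B, HDAC5, HIST1H2AC, KLHL24, BCL6 and PLCL1. KLHL24, on chromosome 3 from 183635568 to 183684477, rose 8.93-fold from 870 ± 157 to 7706 ± 367 normalized counts (3.16 ± 0.13). BCL6, a transcriptional repressor of lymphocytes, rose from 226 ± 47.2 to 1813 ± 204 (3.01 ± 0.18). HDAC5, a class II histone deacetylase, rose from 29.2 ± 9.14 to 291 ± 35.5. Among the same genes, with a mean of at least 100 and no overlap, the largest falls were those of MMP9, TMEM229B, NME1-NME2, ADGRE2, SLCO4A1, FGR, TNFRSF1B and MTND1P23. MMP9, a secreted matrix metalloproteinase on chromosome 20 from 46008908 to 46016561, fell from 228 ± 28.4 to 3.73 ± 2.58 normalized counts (-5.72 ± 0.54; -4.77 with a pseudocount of 5, which weighs more on low values). FGR, a SRC-family kinase, fell from 754 ± 48.7 to 75.3 ± 20.7, and TNFRSF1B, which encodes a TNF receptor, from 632 ± 203 to 75.5 ± 25.8. NME1-NME2 is a read-through transcript that shares sequence with NME1; its adjusted p of 0.0367 ranged from 0.0044 to 0.154 over 16 alternative settings and missed the threshold in 6, among them those without DMSO replicate 1, 2 or 3. Without MB1-47 replicate 1, NME1-NME2 changed by -1.77 in place of -3.71 and TMEM229B by -2.66 in place of -3.78. Without MB1-47 replicate 2 they changed by -4.61 and -4.56, and without MB1-47 replicate 3 NME1-NME2 changed by -4.76; no other named gene moved by more than 1.5-fold when any 1 library was left out. With a pseudocount of 5 NME1-NME2 changed by -2.91. MTND1P23 is a nuclear copy of MT-ND1 and can share its reads.

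Of 32 fixed lists tested with camera, 22 passed the threshold, 17 toward lower and 5 toward higher values. With a correlation estimated from the data, 2 lists passed, MYC-linked ribosome biogenesis (adjusted p = 0.0488) and DNA replication (adjusted p = 0.0432); for the others the adjusted p with an estimated correlation is given beside each list. Counts adjusted over the list alone were the same as those over all genes tested unless given. With equal library totals no list past the threshold turned in direction, but 6 cytosolic ribosomal protein genes were then higher and 11 lower, 3 mitochondrial chaperone and import genes were higher, and 1 gene each was higher among complex I, glycolysis and fatty acid genes. Many lists that fell also had fewer genes called lower. Complex I then had 18 in place of 24 and mitochondrial ribosomal proteins 39 in place of 44. Glycolysis had 15 in place of 18 and NOTCH1 targets 10 in place of 12.

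**Figure D1:**
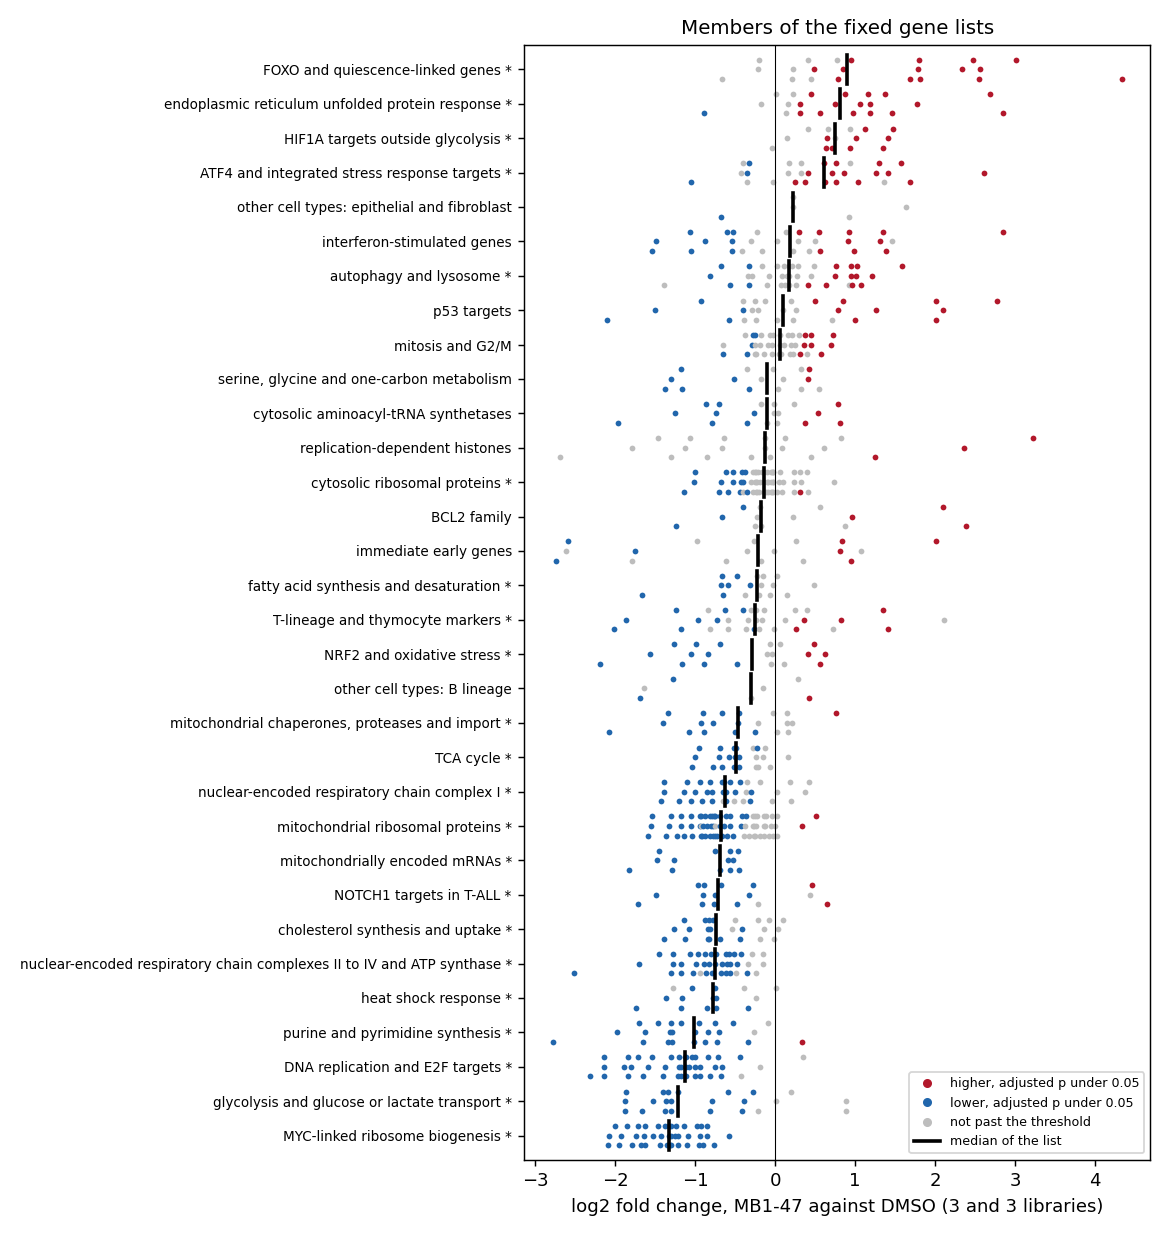
Log2 fold change of MB1-47 against DMSO (x axis) for each tested member of the 32 fixed gene lists (y axis), with lists ordered by their median. Red points are genes higher and blue points genes lower at an adjusted p under 0.05, grey points are genes not past that threshold, black bars are list medians, and an asterisk marks the 22 lists past the threshold in camera; all 41 points of the MYC-linked ribosome biogenesis list are blue.

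Genes of ribosome biogenesis and other growth genes linked to MYC fell together. All 41 members were lower, with a median of -1.33 (camera adjusted p = 9.9e-27). PPAN changed by -2.09 ± 0.20, NOP16 by -2.08 ± 0.18 and MYBBP1A by -2.00 ± 0.11, all factors of the nucleolus. MYC itself, on chromosome 8 from 127735434 to 127741434, fell from 16621 ± 528 to 9014 ± 1450 normalized counts (-0.89 ± 0.11), a 1.86-fold change with an adjusted p of 7.7e-05. Purine and pyrimidine synthesis genes also fell: 22 of 25 were lower and CTPS2 (added, 0.33 ± 0.12) was higher (adjusted p = 9.0e-14; adjusted p = 0.107 with an estimated correlation; 23 lower adjusted over the list alone). Among them, NME1 changed by -2.78 ± 0.22, PFAS by -1.97 ± 0.13 and PAICS by -1.70 ± 0.07, the last 2 being enzymes of purine synthesis. Of 62 genes for cytosolic ribosomal proteins, 15 were lower, RPL22 (added) was higher and 46 did not pass, with a median of -0.14; RPL35, RPL9 and RPS15 fell by 1.14, 1.01 and 1.01 on the log2 scale. That list's camera call (adjusted p = 0.0135; adjusted p = 0.647 with an estimated correlation) was lost in 5 of 16 alternative settings, where the adjusted p ranged from 0.00072 to 0.616, including those without MB1-47 replicate 1 (0.127) or DMSO replicate 3 (0.121).

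DNA replication genes and other E2F targets fell while mitosis genes did not shift as a group. Of 42 replication genes, 39 were lower (40 adjusted over the list alone), none was higher, and the median was -1.12 (adjusted p = 9.1e-24). The 3 that did not pass, all added, were LIG1 (-0.42), CCNA2 (-0.19) and E2F8 (0.34). MCM4, a subunit of the replicative helicase on chromosome 8 from 47960185 to 47978160, fell 4.96-fold from 19050 ± 1559 to 3846 ± 390 normalized counts. UHRF1, which maintains DNA methylation, changed by -2.14 ± 0.09, and GINS2, another helicase component, by -2.14 ± 0.23. Of 39 mitosis and G2/M genes, 8 were higher, 5 lower and 26 did not pass (median 0.06, adjusted p = 0.529). CDC25C (0.72 ± 0.13) and CENPE (0.69 ± 0.13) were higher and MAD2L1 (-0.65 ± 0.10) was lower, as were the added genes BUB1B, FOXM1, KIF11 and BUB1. With equal library totals the mitosis list had 13 genes higher and 1 lower. MKI67, a marker of cycling cells, stood at 7866 ± 1607 with DMSO and 9596 ± 985 with MB1-47 (0.30 ± 0.13, adjusted p = 0.10); it passed the threshold in 4 of 16 alternative settings, 1 of them without DMSO replicate 2 (adjusted p = 0.00657; range 0.00657 to 0.312). The mean change of the replication list minus that of the mitosis list was -1.25 ± 0.04. Over all 10 splits of the libraries into 3 and 3 the exact permutation p of that difference, a test added after the data were seen, was 0.1, the lowest that this design can give.

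Replication-dependent histone genes did not pass as a list (adjusted p = 0.529), and their median (-0.13) and mean (-0.16 ± 1.08) were negative while camera's direction was up. The DMSO libraries lay far apart in this list, at -1.34, 2.14 and -0.79 around their mean for replicates 1, 2 and 3, against -0.23, -0.01 and -0.23 for the MB1-47 libraries. HIST1H2AC (from 144 ± 33.7 to 1331 ± 142), HIST1H3E (2.36 ± 0.38) and HIST1H4I (1.25 ± 0.39) were higher, none was lower, and 2 were higher adjusted over the list alone. HIST1H4I missed the threshold without MB1-47 replicate 1, MB1-47 replicate 3 or DMSO replicate 1 (adjusted p over 16 settings 0.0177 to 0.127), and the list passed without DMSO replicate 2 (adjusted p = 0.0111; range 0.0111 to 0.954). These genes are also near-identical copies, so their values are uncertain on both counts.

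**Figure D2:**
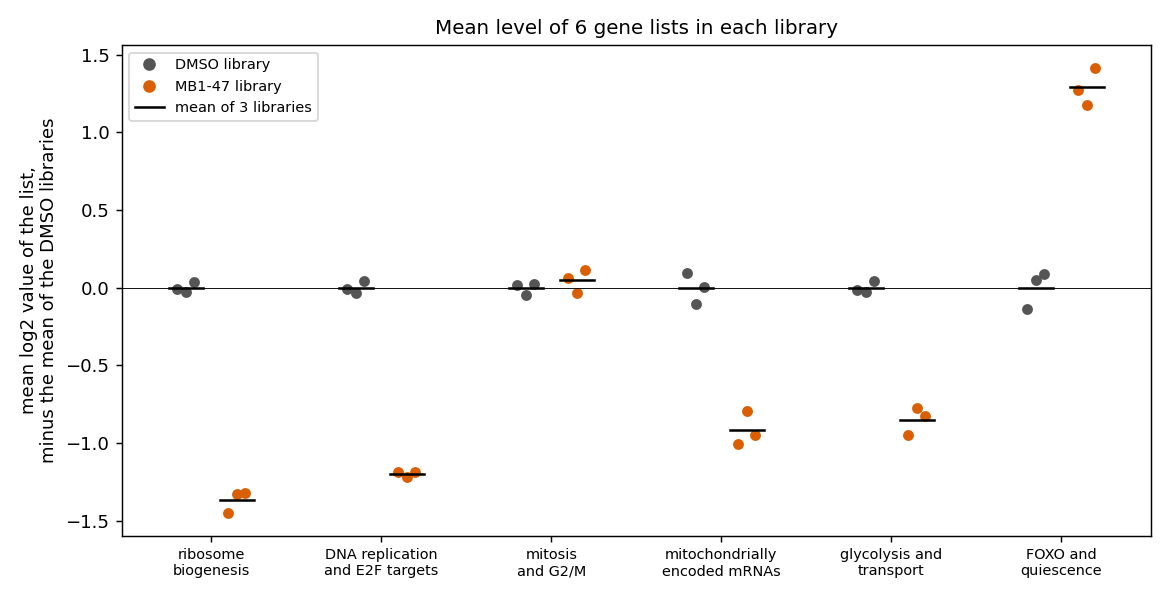
Mean log2 value of 6 fixed gene lists in each library, minus the mean of the 3 DMSO libraries (y axis, log2 units). Grey points are DMSO libraries, orange points MB1-47 libraries and black bars their means; the DNA replication list averages -1.20 with MB1-47 and the mitosis list 0.05.

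Transcripts of the respiratory chain fell from both genomes. All 13 mitochondrially encoded mRNAs were lower, with a median of -0.68 (adjusted p = 9.8e-09; adjusted p = 0.139 with an estimated correlation). Their summed share of all normalized counts was 1.37% ± 0.0619 with DMSO and 0.924% ± 0.0837 with MB1-47 (SD, n = 3). MT-ND2, a complex I subunit at positions 4470 to 5511 of the mitochondrial genome, fell from 47914 ± 4869 to 17433 ± 1212 (-1.46 ± 0.09). MT-ND5 changed by -1.48 ± 0.09 and MT-ND6, which is encoded on the opposite strand, by -1.82 ± 0.13. MT-CO1 (added), a complex IV subunit and the most abundant of these mRNAs, changed by -0.46 ± 0.08.

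Of the nuclear genes for complex I, 24 of 36 were lower and none higher (27 lower adjusted over the list alone; adjusted p = 5.6e-07; adjusted p = 0.202 with an estimated correlation), with NDUFB3 at -1.43 ± 0.23, NDUFS5 at -1.39 ± 0.12 and NDUFB6 at -1.38 ± 0.15. Of those for complexes II to IV and ATP synthase, 32 of 39 were lower and none higher (33 adjusted over the list alone; adjusted p = 1.1e-13; adjusted p = 0.129 with an estimated correlation). ATP5MC1, which encodes the membrane ring subunit of ATP synthase, fell 5.69-fold from 2093 ± 178 to 368 ± 39.9 normalized counts, and ATP5MF and UQCR11 changed by -1.70 ± 0.25 and -1.46 ± 0.19. Mitochondrial ribosomal protein genes were lower in 44 of 72 cases (46 adjusted over the list alone; adjusted p = 1.2e-10; adjusted p = 0.129 with an estimated correlation), led by MRPL23, MRPL11 and MRPL12, while MRPL10 and MRPL49 (both added) were higher. Among mitochondrial chaperones, proteases and import factors, 13 of 21 were lower (14 adjusted over the list alone) and OMA1 (added, 0.76 ± 0.19), a protease activated by loss of membrane potential, was higher (adjusted p = 0.00064; adjusted p = 0.178 with an estimated correlation). HSPE1 changed by -2.08 ± 0.13 and HSPD1, its chaperonin partner, by -1.33 ± 0.07. TCA cycle genes were lower in 15 of 23 cases, with FH at -1.04 ± 0.08 and PC at -0.94 ± 0.21, and IDH3A fell from 4143 ± 306 to 2069 ± 183 normalized counts (adjusted p = 3.6e-06; adjusted p = 0.127 with an estimated correlation). TFAM, which packages mitochondrial DNA and helps start its transcription, fell from 6831 ± 778 to 3836 ± 303, and UCP2, a carrier of the uncoupling protein family, from 1972 ± 155 to 757 ± 130. PPARGC1A, a coactivator of mitochondrial biogenesis, was below the filter, at 2.17 ± 1.07 with DMSO and 0.967 ± 1.01 with MB1-47.

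Glycolytic genes were lower while other targets of HIF1A were higher. Of 23 genes for glycolysis and glucose or lactate transport, 18 were lower and none higher, with a median of -1.21 (adjusted p = 6.2e-10; adjusted p = 0.127 with an estimated correlation). LDHA, which makes lactate from pyruvate and lies on chromosome 11 from 18394388 to 18408425, fell 3.68-fold from 52009 ± 5342 to 14087 ± 858 normalized counts. ENO1 fell from 41851 ± 2533 to 11476 ± 1409 and ALDOA from 17892 ± 2754 to 4890 ± 542. In contrast, 9 of 15 HIF1A targets outside glycolysis were higher and none lower (adjusted p = 1.2e-05; adjusted p = 0.128 with an estimated correlation), with NDRG1 at 1.47 ± 0.22, BHLHE40 at 1.41 ± 0.12 and VEGFA, an angiogenic factor, at 1.35 ± 0.09.

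Lipid synthesis genes were lower. Of 24 genes for cholesterol synthesis and uptake, 15 were lower (16 adjusted over the list alone) and none higher (adjusted p = 5.6e-07; adjusted p = 0.126 with an estimated correlation), with ACAT2 at -1.38 ± 0.12 and DHCR7 at -1.27 ± 0.14. Of 17 genes for fatty acid synthesis and desaturation, 7 were lower and none higher (adjusted p = 0.00333; adjusted p = 0.139 with an estimated correlation). FASN, the fatty acid synthase, fell from 12509 ± 1164 to 3963 ± 284, SCD changed by -0.67 ± 0.07 and ACLY by -0.66 ± 0.07. The list for serine, glycine and folate metabolism did not pass (6 of 16 lower and 2 higher, 5 and 4 under equal totals, adjusted p = 0.152): MTHFD1 (-1.38 ± 0.08) and TYMS (-1.17 ± 0.08) were lower, and SHMT2 and SLC1A4 (both added) were higher.

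Stress response genes of the endoplasmic reticulum and the integrated stress response rose. Of 22 unfolded protein response genes, 16 were higher and CANX (added, -0.89 ± 0.32), a lectin chaperone, was lower, though not under equal totals (18 higher, 0 lower; adjusted p = 6.5e-09; adjusted p = 0.127 with an estimated correlation). ERN1, which encodes the stress sensor IRE1, rose 7.17-fold from 854 ± 133 to 6140 ± 1026, DNAJB9 6.42-fold and SEL1L 3.43-fold. Of 29 targets of ATF4, 16 were higher and 3 lower (18 and 3 adjusted over the list alone; adjusted p = 2.1e-05; adjusted p = 0.127 with an estimated correlation). TRIB3, a pseudokinase induced in this response and located on chromosome 20 from 362835 to 397559, rose 6.09-fold from 9835 ± 772 to 59739 ± 602 normalized counts. PPP1R15A, which directs dephosphorylation of eIF2α, changed by 1.69 ± 0.15 and DDIT3, the transcription factor CHOP, by 1.57 ± 0.14. The 3 lower genes, all added, were ALDH18A1 (-1.05 ± 0.09), SLC7A5 (-0.35 ± 0.09) and PSPH (-0.32), which serve amino acid synthesis and uptake; under equal totals 19 genes of the list were higher and 1, ALDH18A1, lower. The ATF4 transcript itself changed by 0.24 ± 0.07 (adjusted p = 0.0200; range over 16 settings 0.00013 to 0.0823) and missed the threshold in 4 settings, including those without MB1-47 replicate 3, DMSO replicate 1 or DMSO replicate 2. Cytosolic aminoacyl-tRNA synthetases went both ways and did not pass as a list (4 higher, 8 lower of 19; 5 higher adjusted over the list alone; 5 and 6 under equal totals; adjusted p = 0.286). VARS, FARSB and RARS were lower by 1.96, 1.25 and 0.87 on the log2 scale, and AARS, WARS, QARS and CARS (all added) were higher.

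Cytosolic heat shock genes went the other way. Of 15 genes, 11 were lower and none higher (adjusted p = 1.5e-07; adjusted p = 0.139 with an estimated correlation). HSP90AA1 fell from 148693 ± 7457 to 44429 ± 1454 (-1.74, and -1.13 with quantile normalization), HSP90AB1 from 92903 ± 2173 to 36276 ± 2134, and AHSA1, a co-chaperone of HSP90, by 1.18 on the log2 scale. Of 20 genes of the NRF2 and oxidative stress list, 10 were lower and 4 higher (adjusted p = 0.0163; adjusted p = 0.423 with an estimated correlation). PRDX1, a peroxidase, fell 4.54-fold from 18569 ± 1754 to 4082 ± 149, and TXN changed by -1.57 ± 0.09. The 4 higher genes, all added, were SLC7A11 (0.62 ± 0.09), NFE2L2 (0.56 ± 0.10), FTL (0.48 ± 0.07) and CAT (0.42 ± 0.10).

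Genes linked to FOXO factors and to growth arrest were higher. Of 22 genes, 14 were higher and none lower (17 higher and 1 lower adjusted over the list alone), with a median of 0.90 (adjusted p = 2.6e-07; adjusted p = 0.107 with an estimated correlation). Among members past the threshold with a mean of at least 50, BCL6 rose most. CCNG2, an atypical cyclin, rose 5.90-fold from 1085 ± 127 to 6412 ± 865, and PIK3IP1, an inhibitor of PI3-kinase, changed by 2.47 ± 0.31. SESN3 (added), with a lower mean of 21.4 over all libraries, changed more than BCL6 (4.33 ± 0.93). TXNIP, which limits glucose uptake, changed by 0.48 ± 0.14; its adjusted p of 0.0170 ranged from 0.00368 to 0.0862 over 16 settings and missed the threshold in 3, including those without MB1-47 replicate 3 or DMSO replicate 3. Autophagy and lysosome genes were higher in 12 of 39 cases and lower in 5 (14 and 5 adjusted over the list alone; 19 and 3 under equal totals; adjusted p = 0.0143; adjusted p = 0.298 with an estimated correlation). WIPI1 (1.58 ± 0.14), FNIP1 (1.21 ± 0.11) and RRAGD (1.08 ± 0.12) were higher, and GLA, ATG7, ATP6V1B2 and ULK1 (all added) were among the lower genes.

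Targets of p53 went both ways, with 9 higher and 5 lower of 27 (adjusted p = 0.318). TP53INP1 changed by 2.78 ± 0.26 and BBC3, the pro-apoptotic protein PUMA, by 2.10 ± 0.40. CDKN1A, the cell cycle inhibitor p21, fell from 91.3 ± 24.3 to 20.9 ± 7.67, and AEN, TRIAP1, PLK3 and PMAIP1 (all added) were also lower. In the BCL2 family 3 of 13 were higher and 3 lower, and the list did not pass (adjusted p = 0.893; its median of -0.18 and mean of 0.30 differ in sign). BMF (2.38 ± 0.21) and BBC3, which promote apoptosis, and BCL2 (added, 0.96 ± 0.08), which opposes it, were higher, and BID (-1.23 ± 0.14), BCL2L12 and PMAIP1 (both added) were lower. Immediate early genes were higher in 4 and lower in 3 of 18 cases (4 and 4 adjusted over the list alone; adjusted p = 0.793). EGR1 fell from 4955 ± 581 to 751 ± 142, DUSP2 changed by -2.59 ± 0.29 and IER2 (added) was lower, while BTG2 (2.02 ± 0.12) and the added genes KLF6, JUN and JUND were higher.

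**Figure D3:**
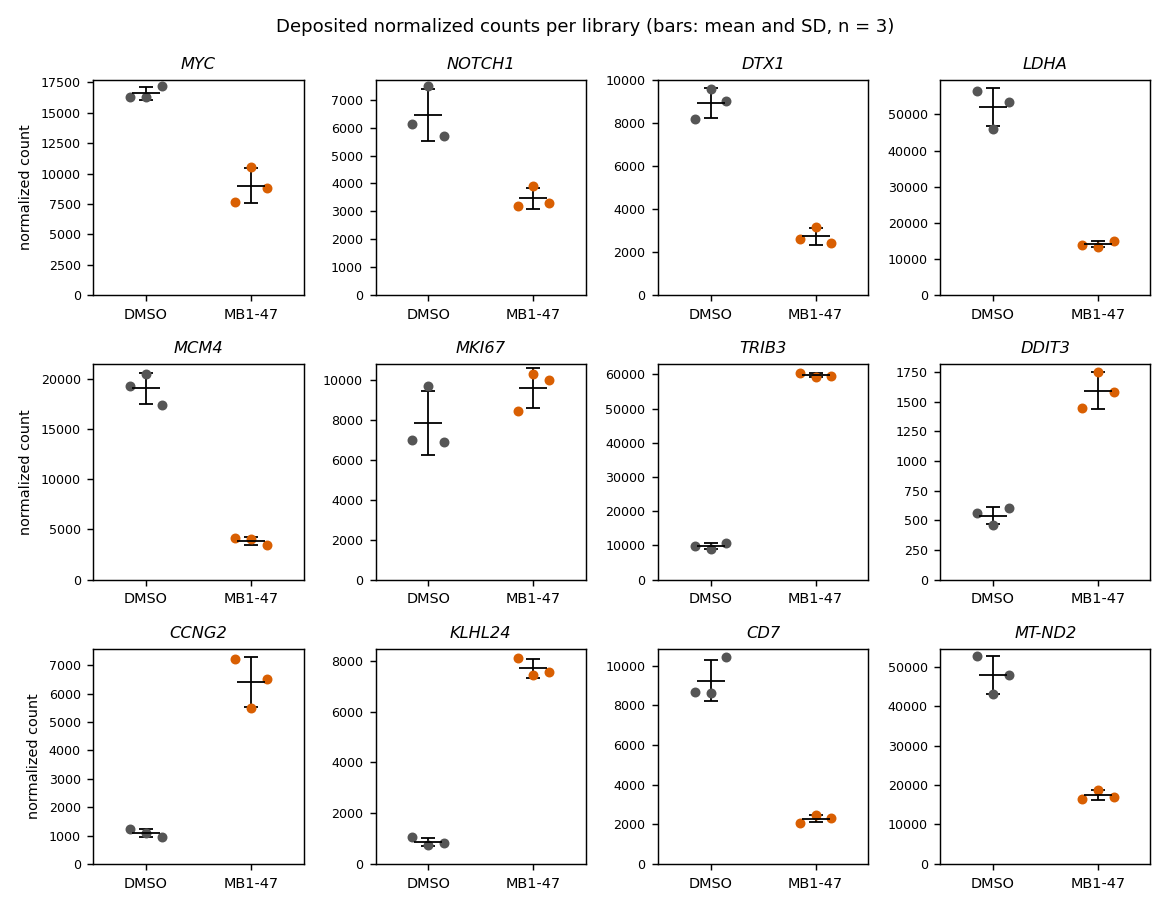
Deposited normalized counts (y axes, linear and starting at 0) of 12 genes in the 3 DMSO libraries (grey) and the 3 MB1-47 libraries (orange), with bars for the mean and SD. TRIB3 rises from 9835 to 59739 and LDHA falls from 52009 to 14087, with no overlap between groups, whereas the MKI67 values of the groups overlap.

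NOTCH1 and its targets were mostly lower. Of 16 tested genes, 12 were lower (13 adjusted over the list alone) and TRIB2 (0.47 ± 0.10) and LZTFL1 (0.65 ± 0.13), both added, were higher (adjusted p = 0.00016; adjusted p = 0.107 with an estimated correlation). NOTCH1, the receptor and T-ALL oncogene on chromosome 9 from 136494433 to 136545786, fell from 6442 ± 935 to 3471 ± 379 normalized counts (-0.89 ± 0.12). DTX1 fell 3.28-fold from 8966 ± 699 to 2740 ± 381, SHQ1 changed by -1.49 ± 0.10, and HES1, a direct transcriptional target, by -0.97 ± 0.14. MYC is also on this list.

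T-lineage markers went both ways. Of 32 genes, 9 were lower and 5 higher. The list's call (adjusted p = 0.0491; adjusted p = 0.139 with an estimated correlation) was lost in 10 of 16 alternative settings, with a range from 0.0267 to 0.128, among them those without MB1-47 replicate 1 (0.0739), MB1-47 replicate 3 (0.0621), DMSO replicate 2 (0.0638) or DMSO replicate 3 (0.0534). CD7 fell from 9248 ± 1039 to 2282 ± 181 and CD1A, a cortical thymocyte antigen, from 1351 ± 75.3 to 371 ± 25.3. CD28, a costimulatory receptor, changed by 1.41 ± 0.21, and DNTT, TOX, SATB1 and BCL11B (all added) were also higher. Of 30 interferon-stimulated genes, 10 were higher and 9 lower (11 and 9 adjusted over the list alone; 13 and 8 under equal totals; adjusted p = 0.701): ISG20 changed by 2.85 ± 0.39, IFI6 by -1.54 ± 0.13 and IFITM2 by -1.49 ± 0.14.

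The B-lineage list did not pass (2 lower, 1 higher of 7; adjusted p = 0.152), although CD79A was abundant and fell from 16526 ± 573 to 6826 ± 391, and IGLL1 changed by -1.69 ± 0.20. BLK (added) averaged 1001 with DMSO and 901 with MB1-47 (adjusted p = 0.398). EBF1 changed by 0.42 ± 0.15, with an adjusted p of 0.0471 that ranged from 0.0148 to 0.164 and missed the threshold in 9 of 16 settings, including those without MB1-47 replicate 2, MB1-47 replicate 3, DMSO replicate 2 or DMSO replicate 3. Of the epithelial and fibroblast markers, PDGFRB (-0.67 ± 0.14) was the only one of 5 past the threshold (adjusted p of the list = 0.844); VIM (added) averaged 17684 with DMSO and 20705 with MB1-47 (0.22 ± 0.08, adjusted p = 0.0558), and passed under equal totals (adjusted p = 0.00653). Of the myeloid and erythroid markers, which were too few to test as a list, FCER1G (added) averaged 9.24 with DMSO and 14.7 with MB1-47, and CSF3R (added) 8.31 and 14.5.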

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

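Equal library totals and the removal of trends on GC content and transcript length were chosen after seeing the data; the other settings were planned. Over 10 settings that kept all libraries, 4261 to 5397 genes passed, 2015 to 3336 of them higher, 2061 to 2715 lower and 1302 to 1485 changed at least 2-fold. With a library left out, 4172 to 4746 genes passed, 1973 to 2321 higher, 2132 to 2494 lower and 1285 to 1457 at least 2-fold, and 79.0% to 87.3% of the original calls were kept. The number of lists past the threshold was 20 to 22 with a library left out. Camera with an estimated correlation called 2 lists and fry, which tests a list by itself, called 26. The cause of that gap was not tested. Correlation above the preset 0.01 is not the whole reason for the few camera calls. The NOTCH1 list had an estimated correlation of -0.029, yet its unadjusted camera p went from 7.8e-05 at the preset to 0.0133. For the T-lineage list, with -0.0067, it went from 0.0337 to 0.0720. Apart from camera with an estimated correlation and fry, 20 of the 22 lists passed in every setting, and the cytosolic ribosomal protein and T-lineage lists did not. Of 114 named genes tested, 108 passed in every setting; ATF4, EBF1, HIST1H4I, MKI67, NME1-NME2 and TXNIP did not. No named gene changed sign, and no list past the threshold changed camera direction. Of the lists not past it, the camera direction of the BCL2 family, histone, and epithelial and fibroblast lists turned in some settings, and under equal totals the median of the aminoacyl-tRNA synthetase list went from -0.11 to 0.02 and that of the serine list from -0.10 to 0.03. Too few epithelial and fibroblast markers were left to test with the filter at 50, without MB1-47 replicate 2 or without DMSO replicate 2. Replicate numbers were shared between the groups, but deviations from the group means correlated by only 0.00724 to 0.0566 between libraries of the same number, so the numbers were not taken as pairs; 3 of 6 libraries correlated best with their own number. With the replicate block 5246 genes and 21 lists passed. Count models (DESeq2 and edgeR) were planned for recovered whole reads and were not run, because whole reads were not recovered; the depth is unknown, so its effect on low genes could not be assessed.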

Other observations

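Some gene families outside the fixed lists were chosen after their values were seen, so their counts only describe them; camera was run on these 9 families, but a test of groups picked by their values restates the choice and its p-values are left out. Proteasome subunits were lower in 35 of 42 cases and higher in 0, with the same counts under equal totals; PSMD3, of the regulatory particle, changed by -1.08 ± 0.08. Small nuclear ribonucleoproteins of the spliceosome were lower in 11 of 12 and higher in 0 (9 and 0 under equal totals), nucleoporins lower in 15 of 20 and higher in 0 (13 and 1), heterogeneous nuclear ribonucleoproteins lower in 14 of 23 and higher in 2 (13 and 3), cytosolic chaperonin subunits lower in 8 of 9 and higher in 1 (8 and 1), and inner membrane translocases lower in 14 of 16 and higher in 0 (11 and 0). ZNF genes were higher in 100 and lower in 33 of 460 cases (146 and 17 under equal totals), SEC genes higher in 10 and lower in 1 of 25 (13 and 0), and KLHL genes higher in 12 and lower in 4 of 26 (15 and 2). Of all 13465 genes tested, 2458 were higher and 2667 lower. The share of ZNF genes called higher was thus near that of all genes, 327 did not pass, and few were lower. As a check that does not pick groups by value, though added after the data were seen, camera was run on all 218 groups of at least 10 protein-coding genes that share the first 3 letters of their symbols: 28 passed at the preset correlation, 19 lower and 9 higher, and 0 with an estimated correlation (lowest adjusted p = 0.528). Even the PSM group of 47 genes (median -0.86, camera adjusted p = 1.4e-15 at the preset) reached only that lowest value, which many groups shared. With an estimated correlation camera could thus hardly call any group here, and the 0 does not show that the groups were unchanged.

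Genes often used as references also moved. ACTB fell from 120534 ± 7445 to 40171 ± 2664 normalized counts (SD, n = 3; -1.59 ± 0.08) and GAPDH from 296511 ± 31301 to 120391 ± 10489 (-1.30 ± 0.10), and under equal totals they changed by -1.46 and -1.17. EEF1A1 changed by 0.14 ± 0.09 (adjusted p = 0.253) and by 0.27 under equal totals, where it passed (adjusted p = 0.00871). As single genes chosen after their values were seen, TAGLN2 changed by -2.52 ± 0.16, FLNA by -1.82 ± 0.15 and PFN1 by -1.60 ± 0.15. The 4 YPEL genes tested were higher, from YPEL1 at 1.20 ± 0.17 to YPEL3 at 3.38 ± 0.36. CDKN1B, the cell cycle inhibitor p27, rose from 2162 ± 161 to 6945 ± 151, and BTG1, an anti-proliferative factor, from 2492 ± 473 to 8656 ± 478. TWNK (-1.34 ± 0.11), TFAM (-0.83 ± 0.10) and POLRMT (-0.57 ± 0.14), also chosen singly, were lower, and TFB2M (-0.37 ± 0.11) lost its call under equal totals (adjusted p = 0.0976).

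For the patterns weighed here, the tests for fewer cycling cells, for reads shared with nuclear copies and for scaling of the mitochondrial mRNAs were chosen after the result was seen. Removal of the trends on GC content and transcript length was also added after the data were seen, with its expected outcome written before its result was computed. The splits of the libraries were set before.

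The first pattern is the extent of change. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 with the most genes past the threshold in limma (5125, highest other 0), as it was for genes higher (2458, highest other 0), genes lower (2667, highest other 0), genes changed at least 2-fold (1446, highest other 0) and lists (22, highest other 17). In the other splits at most 394 genes had an unadjusted p under 0.05, a share of 2.93%, which is below what that cutoff gives by chance. Each of these splits has libraries of both groups on each side, so the treatment difference widens the spread within sides. Gene counts near 0 were thus likely in advance, and they do not measure what chance alone would give. The other splits called 12 to 17 lists, and they keep part of the treatment difference. With each gene's group difference taken out, they still called 0 to 9 lists at the preset correlation and 0 with an estimated one. The preset correlation thus understates the error of the lists. How far each of these accounts for the 12 to 17 calls was not tested. After each library's trend on GC content and transcript length was removed, 90.9% of the 22 lists past the threshold kept their direction and call, which argues against those trends as the cause of most list changes.

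The second pattern is that DNA replication genes fell and mitosis genes did not. With the trends on GC content and length removed, the difference between the lists was -1.18 ± 0.02 (-1.25 before), which argues against such a bias. A smaller share of cycling cells was a further candidate, which would lower both lists. The mitosis list changed by 0.048 ± 0.050 on average against -1.20 for replication. These means also define the pattern, so the comparison restates it and is not a separate test. It shows only that the lists did not fall together. A hypothesis that stays open is that cells left S phase or did not enter it while those in G2 or mitosis persisted, which may be seen in a cell cycle profile; no cell cycle measurement was analysed here, and a direct effect on transcription of E2F targets would look alike.

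The third pattern is that mitochondrially encoded mRNAs fell. The table holds 27 nuclear copies of these genes, with 1.71% of the summed signal in DMSO. The sum of mitochondrial mRNAs and nuclear copies changed by -0.71 ± 0.08 on the log2 scale, against -0.70 ± 0.08 without the copies. With so small a share, adding the copies could hardly alter the sum. The copies themselves changed by -1.27 ± 0.06, which argues against reads moving from the mRNAs to these copies. Under equal totals the median of the 13 mRNAs was -0.56 ± 0.11, so the fall did not depend on the choice between these scalings. Equal totals moved the median of all genes only from 0.02 to 0.15 and could hardly have undone the fall. Without a spike-in, a change in total RNA could not be tested this way. Reduced transcription and fewer mitochondrial genomes per cell may each contribute and stay open, since no measure of mitochondrial DNA was analysed here.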
